A study of Rattus norvegicus with 2 samples.

How the data were processed

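Gene expression was measured by RNA sequencing in 2 wild-type libraries of a rat embryonic stem cell line, each from total RNA extracted with Trizol and cleaned on columns, per the labels. Libraries were made with the TruSeq RNA kit and sequenced as paired 50-bp reads. The authors deposited 1 table of RPKM values, with 1 column per library, matched to the samples by title. Per the submitters' processing notes, CASAVA 1.8 and TopHat 1.4.0 were used, and the builds named are rn5 and Rnor_5.0. The counting tool, the annotation and the treatment of reads that map to several places are not given in the sources used here. RNA integrity was analysed, per the labels' protocols, which give no value per sample.

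The deposited table held 23716 rows, all protein coding, for 23282 Entrez gene identifiers on 20 autosomes and the X chromosome. Some symbols had turned into calendar dates (26 genes), and 2 such dates each stood for 2 genes, so rows were joined by Entrez identifier rather than by symbol as first planned. The rows of 420 genes with more than 1 row were summed. No column of other samples was present.

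RPKM is not a count, so no count model was used. Read totals of 2991184 and 3050685 are those that made the most rows above 0 with a locus under 6000 bp come out as whole reads, taking the locus as the gene model. This held in 527 of 2700 such rows in replicate 1 and 525 of 2688 in replicate 2. Whole reads in both libraries, within a relative tolerance of 3e-07, came out for 78.3% of the 12970 rows above 0 in both, using the shortest gene model length from 60 bp to 20000 bp that made both whole. Over 3000 rows drawn at random from these, 78.4% came out whole, and 1.30% after a slight random shift of the values. In the 226 of them at 100 RPKM or more the shares were 62.4% and 13.3%, so chance matches are more common there. Lengths found this way can be too short by a common factor, and the reads served only to compare the libraries with sampling noise and to estimate model length. At 10 RPKM a model of 2 kb holds about 59.8 reads in replicate 1, a counting error of 12.9%.

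With 1 group of 2 samples no test between groups exists. Levels are means ± SD over 2 replicates, in RPKM, and differences use log2(RPKM + 1), which understates changes of low genes. A mean of at least 1 RPKM counted as detected. The design, the alternatives and 24 gene lists, those whose results the report gives, were fixed before the data were examined. Each list median was placed among 10000 random lists of the same size, drawn from all 23282 genes. Of these, 8902 were listed at 0 in both replicates, so a high percentile does not by itself place a list above typical detected genes. List ratios between replicates were placed among 10000 random lists matched on mean expression in 20 bins, and chromosome ratios among 10000 random gene sets. List members without a row were not analysed here (Sall4, Dppa2, Dppa4, Zfp42, Prdm14, Sox3, Znrf3, Tead4, Esx1, Cer1, Foxf1, Sox1, Suz12, Jarid2, H19, Peg3, Peg10, Meg3 and Sesn2).

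The genes named are the 6 highest and 3 lowest of the core, naive, primed, beta-catenin and LIF lists, the 3 highest and 1 lowest of every other list, the 20 highest genes of the table, and the 10 genes at a mean of at least 1 RPKM with the largest ratio between replicates. Some genes that this rule takes are not reported here. Other genes are named where the text says that they were chosen after their values were seen.

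Alternatives were a detection minimum of 0.3 or 3 RPKM, a pseudocount of 0.1, a minimum of 0.1 RPKM for list members, a minimum of 10 RPKM or no minimum for the comparisons between replicates, each replicate alone, rescaling each library to a sum of 1000000, the highest row per gene, list means, and a median-centred replicate 2. Others were added after the data were seen: leaving out members listed at 0, and removing a straight line of the ratio on gene model length or on locus length.

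The procedures were tested on simulated pairs of libraries with counting noise only. With no difference 3.81% of 210 lists fell outside the central 95%. A 1.5-fold change of a list was found in 95.2% of 21 lists, and that of a chromosome in 100.0% of 21 chromosomes. The simulated depth was recovered without error, in libraries where 100.0% of 1500 genes tried came out as whole reads. In the data 78.3% of rows did, so the simulated setting was easier and this check does not cover the other rows. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Names of pseudogenes came from a RefSeq gene table of the GRCr8 assembly, in which 81 of 83 ribosomal protein genes matched by identifier, and none of its coordinates were used.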

Results

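Total RNA from rat (Rattus norvegicus) embryonic stem cells was sequenced in 2 libraries, called biological replicates by the series design. The cells were a line of the Dark Agouti strain from the Rat Resource Center. They were at passage 30, were labelled as having a normal karyotype, and were grown untreated in 2i medium, a medium that holds inhibitors of MEK and of GSK3. Both samples form 1 wild-type group, so the series holds no contrast between conditions. The design asks what the cells transcribe and how closely the replicates match. Gene expression was deposited as RPKM (reads per kilobase of gene model per 1000000 reads) for 23282 genes, with positions on the rn5 build. Steps shared by part of the values point to 2991184 reads behind replicate 1 and 3050685 reads behind replicate 2. At these depths 3 reads in a gene model of 2 kb correspond to 0.501 RPKM in replicate 1 and 0.492 RPKM in replicate 2, a floor that covers counting error only.

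The 3 highest genes of the table encode a glycolytic enzyme, a ribosomal protein and a translation factor. Aldoa, the glycolytic aldolase (Entrez gene 24189, chromosome 1, 205208255 to 205213088), had the highest mean at 2287 ± 7.95 RPKM (SD, n = 2). It was followed by the ribosomal protein gene Rpl4 at 2168 ± 40.2 RPKM and by Eef2, the translation elongation factor, at 2035 ± 8.89 RPKM. The 20 highest genes also held Gpi, Pgk1 and Pgam1 of glycolysis, the glucose transporter gene Slc2a1, Atp5b of the ATP synthase, and the ribosomal protein genes Rplp0, Rpl3 and Rps3. Gstp1, Hsp90ab1, Gnb2l1, Pabpc1, Tubb5 and Bsg were also among them, with Bsg at 943 ± 8.42 RPKM. Together the 20 genes took 6.27% of the summed RPKM in replicate 1 and 6.26% in replicate 2. A mean of at least 1 RPKM was reached by 10814 genes, 46.4% of those listed, and by 10855 genes in replicate 1 and 10768 in replicate 2. A mean of at least 10 RPKM was reached by 6853 genes and of at least 100 RPKM by 932 genes. Another 8902 genes were listed at 0 in both replicates. Genes that every cell uses are among them, such as Rps6, so a listed 0 does not show that a gene was not transcribed. Of 24 gene lists fixed in advance, 18 had 50% or more of their measured members at a mean of at least 1 RPKM.

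Core pluripotency factors were abundant in both replicates. All 11 measured members of the list reached 10 RPKM, and the list median was 177 ± 4.13 RPKM (SD, n = 2), above all 10000 random lists of the same size. Random lists were drawn from all genes listed, those at 0 included. Trim28, a co-repressor that silences retroviral elements, stood highest at 937 ± 25.6 RPKM, followed by Utf1 at 655 ± 14.1 RPKM. Pou5f1, which encodes the transcription factor Oct4 (Entrez gene 294562, chromosome 20, 5833973 to 5838736), was at 584 ± 9.94 RPKM. Its partner Sox2 (Entrez gene 499593, chromosome 2, 140810593 to 140813001) was at 177 ± 4.13 RPKM. The Nodal co-receptor gene Tdgf1 was at 344 ± 14.2 RPKM and L1td1 at 206 ± 0.999 RPKM. Rif1, at 83.1 ± 0.209 RPKM, and the growth factor gene Fgf4, at 44.9 ± 4.43 RPKM, were lower. Nanog, named here after its value was seen, was at 106 ± 3.95 RPKM. Sall4, Dppa2 and Dppa4 were not analysed here.

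Most members of the naive pluripotency list, chosen in advance to mark the preimplantation-like state, were detected, and so were several markers of the primed epiblast. How specific each member is to that state was not tested. Of 14 measured naive factors 11 had a mean of at least 1 RPKM and 9 of at least 10 RPKM, with a list median of 29.3 ± 0.441 RPKM at the 99.9th percentile of random lists. Mybl2 was highest at 158 ± 4.84 RPKM. Klf5 (75.9 ± 1.41 RPKM), Dppa3 (73.0 ± 14.9 RPKM) and Esrrb (70.5 ± 4.95 RPKM) came next, ahead of Tbx3 (42.3 ± 0.275 RPKM) and Klf2 (42.3 ± 0.589 RPKM). Nr0b1, Nr5a2 and Dppa5 were listed at 0 in each replicate. Among 11 measured primed markers 8 had a mean of at least 1 RPKM, and the list median was 12.3 ± 0.770 RPKM, at the 94.9th percentile. The de novo DNA methyltransferase gene Dnmt3b led them at 453 ± 2.53 RPKM, followed by Zic2 at 80.8 ± 0.850 RPKM and Foxd3 at 80.1 ± 8.61 RPKM. Zic5 (19.2 ± 0.611 RPKM), Cldn6 (15.5 ± 1.93 RPKM) and Pou3f1 (12.3 ± 0.770 RPKM) were lower. Otx2 was at 1.00 RPKM in replicate 1 and 0.561 RPKM in replicate 2. Wnt8a was at 0 and 0.194 RPKM, and Fgf5 was listed at 0 in both.

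On the log2(RPKM + 1) scale the naive list median lay above the primed list median by 1.14 ± 0.08 (SD, n = 2), by 1.19 in replicate 1 and 1.08 in replicate 2. The difference was larger than the spread between the replicates, which does not include the choice of list members. With list means in place of medians it was 0.28. The core list lay above the primed list by 3.75 ± 0.05.

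**Figure D1:**
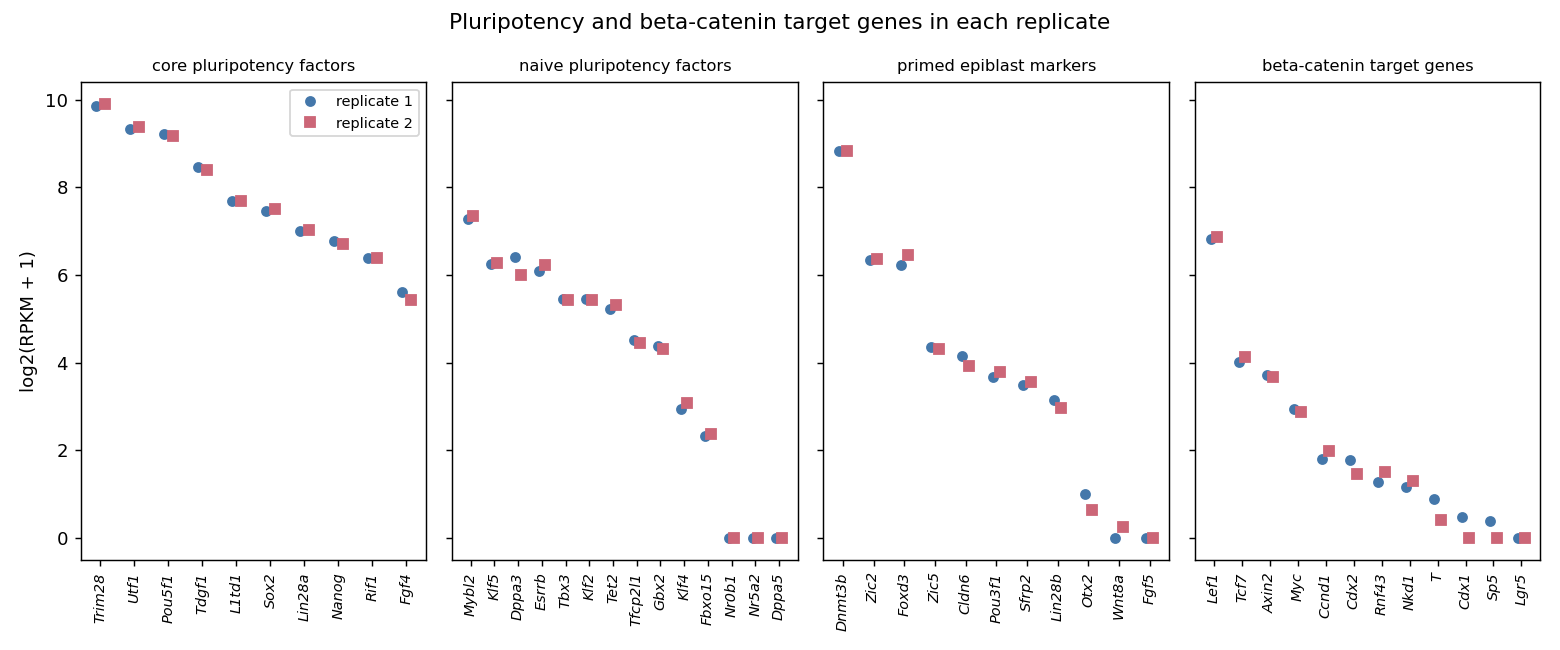
Each point is the log2(RPKM + 1) of 1 gene in 1 replicate, circles for replicate 1 and squares for replicate 2, with a panel each for the core, naive, primed and beta-catenin lists. The core factors shown lie above 10 RPKM in both replicates, while Nr0b1, Nr5a2, Dppa5, Fgf5 and Lgr5 lie at 0 in both.

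Most genes of the LIF and STAT3 pathway were detected. Levels of the targets of beta-catenin, which inhibition of GSK3 stabilises, were uneven. The LIF list includes receptor and kinase genes, so the 2 lists do not compare the output of the pathways. Of 10 LIF and STAT3 pathway genes 9 had a mean of at least 1 RPKM. The receptor gene Lifr was highest at 83.2 ± 8.48 RPKM, followed by Pim1 (35.7 ± 3.47 RPKM), Pim3 (30.3 ± 1.53 RPKM), Stat3 (30.1 ± 2.91 RPKM), the co-receptor gene Il6st (28.7 ± 0.495 RPKM) and the kinase gene Jak1 (23.0 ± 0.553 RPKM). Bcl3 (4.40 ± 0.266 RPKM), Socs3 (1.54 ± 0.564 RPKM) and Junb (0.738 ± 0.514 RPKM) were lowest. The list median of 25.8 ± 0.662 RPKM lay at the 99.4th percentile of random lists, which include genes listed at 0. The median of detected autosomal genes was 16.9 RPKM in replicate 1 and 16.7 RPKM in replicate 2. Of 12 measured beta-catenin targets 8 had a mean of at least 1 RPKM and 3 of at least 10 RPKM, with a median of 1.86 ± 0.105 RPKM at the 65.1st percentile. Lef1, a partner of beta-catenin, was far above the others at 114 ± 2.93 RPKM, followed by Tcf7 at 15.9 ± 0.924 RPKM and Axin2 at 11.9 ± 0.391 RPKM. Myc was at 6.50 ± 0.290 RPKM, Ccnd1 at 2.69 ± 0.331 RPKM and Cdx2 at 2.10 ± 0.486 RPKM. Cdx1 was at 0.397 and 0 RPKM, Sp5 at 0.315 and 0 RPKM, and Lgr5 was listed at 0 in both. Of 12 ERK pathway response genes 11 had a mean of at least 1 RPKM, with a median of 10.3 ± 1.47 RPKM, led by Etv5 at 72.7 ± 2.05 RPKM and Spry2 at 43.2 ± 1.05 RPKM, with Spred1 at 20.6 ± 3.22 RPKM. The immediate early gene Egr1 was listed at 0 in both.

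Markers of differentiated lineages were mostly low or listed at 0. The core and naive lists together lay above each of 8 lineage lists, by 3.11 ± 0.13 (log2, SD, n = 2) over germ cell markers at the least and by 6.04 ± 0.07 over mesoderm, neuroectoderm, and definitive endoderm and gut markers, whose medians were 0. The difference was 4.42 ± 0.18 over trophectoderm, 5.83 ± 0.03 over primitive endoderm, 5.64 ± 0.25 over fibroblast and feeder, and 6.02 ± 0.10 over blood cell markers. Where a list median is 0, the difference equals the level of the pluripotency lists and depends on the pseudocount. With a pseudocount of 0.1 the largest difference was 9.34. Which list came closest depended on the members kept. With only members at 0.1 RPKM or more the smallest difference was 2.34, over primitive endoderm, against 3.26 over germ cell markers. Against random lists of the same size, the 8 list medians lay between the 6.44th percentile (mesoderm) and the 87.2nd (germ cell).

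With all measured members kept, germ cell markers had the highest median of the 8 lists, with 9 of 11 at a mean of at least 1 RPKM. Dppa3, which the naive list also holds, was followed by the meiotic gene Sycp3 at 34.2 ± 4.57 RPKM and the RNA helicase gene Ddx4 at 31.9 ± 0.444 RPKM, and Prdm1 was listed at 0. Of 10 trophectoderm markers 6 had a mean of at least 1 RPKM, with Tfap2c at 106 ± 4.36 RPKM, Krt18 at 61.2 ± 0.168 RPKM and Eomes at 21.9 ± 0.533 RPKM, and Hand1 listed at 0. Of 11 primitive endoderm markers 5 had a mean of at least 1 RPKM. The basement membrane genes Lamb1 (53.5 ± 4.19 RPKM), Col4a1 (26.1 ± 0.773 RPKM) and Lama1 (23.6 ± 5.58 RPKM) were the highest of them, and Foxa2 was listed at 0. Of 10 definitive endoderm and gut markers only Hhex reached 1 RPKM, at 63.5 ± 1.64 RPKM. Cxcr4 was at 0.679 ± 0.147 RPKM, Foxa3 at 0.223 and 0.219 RPKM, and Ttr was listed at 0. Of 12 mesoderm markers Tcf15 (4.95 ± 2.27 RPKM) and Tbx6 (1.06 ± 0.150 RPKM) reached 1 RPKM, and 9, Pax3 among them, were listed at 0. Of 11 neuroectoderm markers Tubb3 (32.3 ± 0.184 RPKM), Map2 (2.52 ± 0.181 RPKM) and Nes (1.28 ± 0.218 RPKM) reached 1 RPKM, and Dcx was listed at 0. None of 8 blood cell markers reached a mean of 1 RPKM, the highest being Cd68 at 0.964 ± 0.182 RPKM. Lyz2 was at 0.281 and 0.275 RPKM, Runx1 at 0.248 ± 0.120 RPKM, and Hbb was listed at 0. The 2 values of Foxa3, like those of Lyz2, differ only by the ratio of the read totals, 1.02, as equal numbers of reads would. Their closeness therefore does not measure precision.

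Of 15 fibroblast and feeder cell markers 5 had a mean of at least 1 RPKM. The fibronectin gene Fn1 stood apart at 717 ± 75.5 RPKM, while Col1a1 was at 4.70 ± 1.86 RPKM, Col3a1 at 2.24 ± 1.30 RPKM and S100a4 listed at 0.

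**Figure D2:**
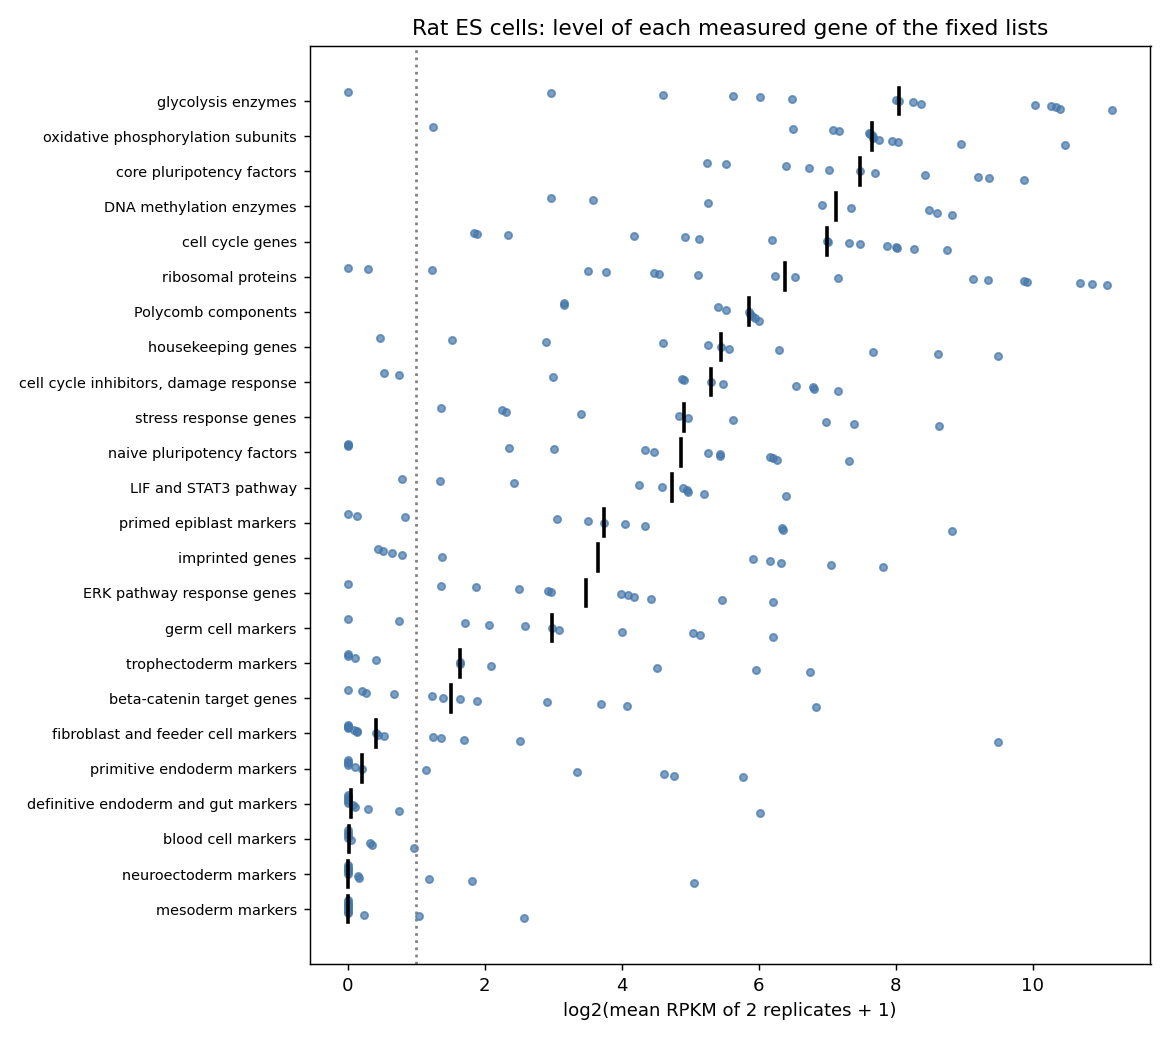
Each point is 1 measured gene of a list, placed by the log2 of its mean RPKM over 2 replicates plus 1, with black bars for list medians and a dotted line at 1 RPKM. The medians of core pluripotency, energy metabolism and cell cycle genes lie towards the right and those of mesoderm, neuroectoderm, blood and gut markers near 0, though some genes, such as Hhex and Slc2a3, lie far from the median of their list.

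Chromatin, cell cycle and metabolic genes were high. The medians of the DNA methylation, Polycomb, imprinted, cell cycle, inhibitor, stress, glycolysis, oxidative phosphorylation, ribosomal and housekeeping lists lay at the 99.6th percentile of random lists or higher. All 8 DNA methylation enzymes had a mean of at least 1 RPKM, with a list median of 141 ± 2.22 RPKM. Beside Dnmt3b, Uhrf1 (387 ± 7.56 RPKM) and Dnmt3l (356 ± 8.004 RPKM) were highest, and Tet1, an enzyme that oxidises methylcytosine, was lowest at 6.82 ± 0.172 RPKM. All 9 measured Polycomb genes were detected, with Ezh2 at 63.2 ± 1.21 RPKM, Cbx7 at 60.4 ± 2.75 RPKM, Ezh1 at 58.8 ± 4.18 RPKM and Bmi1 at 7.90 ± 0.110 RPKM. Of 10 imprinted genes 6 reached 1 RPKM and 5 reached 10 RPKM. Their list median of 30.5 ± 2.40 RPKM is the midpoint of a gap between a gene at 59.3 RPKM and a gene at 1.60 RPKM. The percentile of this list therefore does not describe a typical member. Mest was at 224 ± 0.821 RPKM, Snrpn at 132 ± 6.80 RPKM and Igf2r at 78.9 ± 7.91 RPKM, against 0.360 ± 0.165 RPKM for Dlk1.

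All 16 cell cycle genes were detected, with a median of 127 ± 0.205 RPKM. Pcna was at 427 ± 20.1 RPKM, Cdk4 at 306 ± 2.19 RPKM and Ccnb1 at 259 ± 13.3 RPKM, while the D-type cyclin gene Ccnd2 was lowest at 2.59 ± 1.69 RPKM. Of 11 cell cycle inhibitor and damage response genes 9 reached 1 RPKM, among them Mdm2 (110.3 ± 6.50 RPKM) and Bax (109 ± 7.34 RPKM), with Cdkn2b at 0.441 ± 0.213 RPKM. All 10 stress response genes reached 1 RPKM, with Hspa5 at 393 ± 11.2 RPKM, Hsp90aa1 at 167 ± 0.790 RPKM, Hmox1 at 126 ± 1.58 RPKM and Fos at 1.57 ± 0.758 RPKM.

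Glycolysis enzymes had the highest list median, 263 ± 2.02 RPKM, with 14 of 15 members at 1 RPKM or more. Slc2a3, a glucose transporter gene, was listed at 0. All 14 oxidative phosphorylation genes were detected, with Atp5b at 1424 ± 19.95 RPKM, Atp5a1 at 494 ± 10.3 RPKM, Cox4i1 at 260.0 ± 10.02 RPKM and the cytochrome c gene Cycs at 1.38 ± 0.371 RPKM. Ribosomal protein genes ranged from Rpl4 to Rps6, listed at 0, with 16 of 18 at 1 RPKM or more. Of 11 housekeeping genes 10 reached 1 RPKM. Actb was at 719.8 ± 6.92 RPKM, Ywhaz at 391 ± 14.1 RPKM and Sdha at 202 ± 7.01 RPKM, against 0.764 and 0 RPKM for Hprt1. Low values such as those of Cycs and Hprt1 may be failed estimates, as a listed 0 may be. Cycs had 4 copies described as "-like" among the genes listed, and whether these cost it reads was not tested.

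The replicates resembled each other closely. Across the 10814 genes with a mean of at least 1 RPKM, Pearson's r of log2(RPKM + 1) was 0.989 and Spearman's rho 0.991. Genes are not independent replicates, so no p-value accompanies these. A ratio of RPKM + 1 over 2-fold was seen in 78 genes (0.721%), 26 higher in replicate 2 and 52 higher in replicate 1. Of them 54 had a mean between 1 and 3 RPKM. The SD of the log2 ratio fell from 0.46 among genes at 1 to 3 RPKM to 0.09 among genes at 100 RPKM or more. The gene farthest apart was Tcf24, at 3.91 RPKM in replicate 1 and listed at 0 in replicate 2. LOC691092 (6.97 and 0.859 RPKM), LOC679594 (6.61 and 0.926 RPKM), Ifi27l2b (8.15 and 1.45 RPKM) and LOC494527 (3.20 and 0.138 RPKM) were higher in replicate 1. RGD1560258, Wfdc12, LOC100363434 and Ube2n were at 2.95, 2.82, 2.76 and 2.67 RPKM in replicate 1 and listed at 0 in replicate 2. Gng13 was higher in replicate 2, at 4.76 against 0.515 RPKM. Few reads lie behind values this low. In replicate 1, 3 reads in a gene model of 1 kb correspond to 1.00 RPKM, and in a shorter model to more.

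Reads recovered from the value steps tested whether the libraries differed beyond sampling. Among 2339 gene models with 20 to under 100 reads over both libraries, the chi-square per model was 0.960 (p = 0.914). The chi-square per model was 1.09 (p = 0.00174) among 2186 models with 100 to under 300 reads and 1.26 (p = 1.06e-14) among 2073 models with 300 to under 1000 reads, above sampling noise. A recovered model length can be too short by a common factor, which makes the reads too few and lowers the chi-square, so a value under 1 does not show agreement within sampling noise. Among 215 models as long as their locus, with 20 or more reads, which are free of this, the chi-square per model was 1.15 (p = 0.0645). These tests treat reads as independent and cover counting error only. They compare the libraries, not conditions, and do not show whether the samples came from separate cultures.

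Between the replicates 2 of 21 gene lists with at least 3 members at 1 RPKM lay outside the central 95% of random lists matched on mean expression, where 1.05 would be expected by chance. Fibroblast and feeder cell markers had a median log2 ratio of 0.51 towards replicate 2, at the 99.8th percentile, with all 5 members at 1 RPKM or more higher there. Fn1 was at 664 RPKM in replicate 1 and 771 RPKM in replicate 2, Col1a1 at 3.39 and 6.02 RPKM, and Col3a1 at 1.32 and 3.16 RPKM. Ribosomal proteins had a median log2 ratio of -0.07, at the 2.38th percentile, with 3 of 16 members higher in replicate 2. With 21 lists compared, a list as far out as the fibroblast list arose in 6.56% of random draws. A pseudocount of 0.1 left 1 list outside, with the ribosomal proteins inside the range. With a line of the ratio on locus length removed, chosen after the data were seen, ribosomal proteins lay inside at the 15.1st percentile, germ cell markers outside at the 2.36th, and the fibroblast list still outside.

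No chromosome moved by the amount a gained copy would give. Of 21 chromosomes, chromosome 20 had the largest shift, -0.03 (log2, replicate 2 against replicate 1, 323 genes), outside the central 95% of random gene sets, where 1.05 chromosomes would be expected to fall by chance. A copy gained in all cells of 1 culture would move its genes by 0.58. A copy number shared by both cultures would not show in this ratio.

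**Figure D3:**
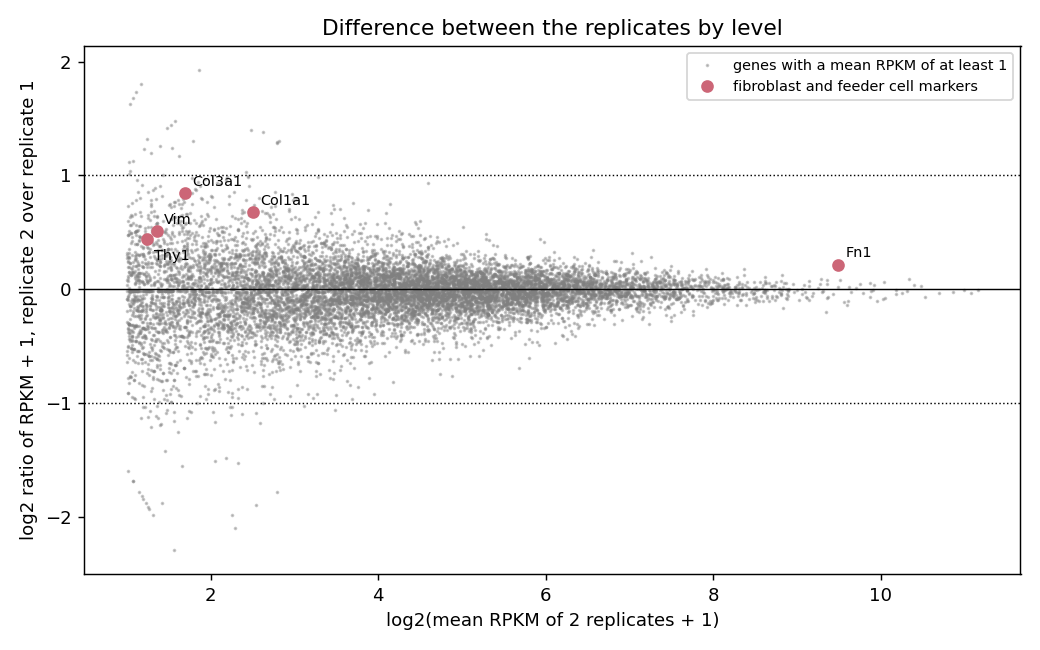
Each grey point is 1 of the 10814 genes with a mean of at least 1 RPKM, with its log2 mean RPKM + 1 on the x axis and its log2 ratio of RPKM + 1, replicate 2 over replicate 1, on the y axis, with dotted lines at 2-fold. The scatter narrows with level, and the 5 fibroblast and feeder cell markers, in red, lie above 0.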

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

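Leaving out members listed at 0 and removing length lines were chosen after the data were seen. No paired analysis was possible because the series has 1 group. Without either replicate the naive minus primed difference ranged from 1.08 to 1.19, the smallest lineage difference from 3.02 to 3.20, the largest from 5.99 to 6.09, and detected genes from 10768 to 10855. With 1 of 2 replicates left out the value is that of the other, so these ranges restate the 2 replicates and add no test. Comparisons between the replicates have no value with 1 left out. Detected genes ranged from 9309 to 12364 over all settings, and lists with 50% or more of their members detected from 18 to 22. The naive minus primed difference stayed above 0 but moved to 1.39 with a member minimum of 0.1 RPKM, 0.28 with list means and 1.55 without members listed at 0. The smallest lineage difference moved to 3.27 with a pseudocount of 0.1 and 2.52 with list means, over germ cell markers as in the main setting. It moved to 2.34 with the member minimum and 2.95 without members listed at 0, now over primitive endoderm markers, whose own main value was 5.83; germ cell markers stood at 3.26 in both. The largest moved to 9.34 with the pseudocount of 0.1, to 5.90 with the member minimum and 5.36 with list means, both now over blood cell markers, and to 7.22 with libraries rescaled to a sum of 1000000. For the largest, by construction a list median of 0 stays at 0 with rescaling and becomes -3.32 with a pseudocount of 0.1; with the other settings the cause was not tested. Pearson's r between replicates was 0.981 with a pseudocount of 0.1, 0.995 with no minimum and 0.991 at 10 RPKM or more, and 257, 151 and 1 genes were over 2-fold apart. Low genes weigh more with the smaller pseudocount and are more or fewer under the other minima, by construction; the cause of the moves in r was not tested. Lists outside the random range numbered 2 of 21 in the main setting, 1 of 21 with a pseudocount of 0.1, 3 of 24 with no minimum, 3 of 19 at 10 RPKM or more, 2 of 21 after removing the locus length line and 0 of 14 after removing the model length line; the fibroblast list could not be tested there, and none of the 14 lay outside before the line was removed, so the loss comes from the smaller gene set. Ribosomal proteins lay inside the random range with a pseudocount of 0.1 and after either line. Germ cell markers lay outside with no minimum, at 10 RPKM or more and after the locus length line, and stress genes at 10 RPKM or more. The other values were levels of single lists, their shifts between replicates, and differences between the pluripotency lists and each lineage list. Of these 227 stayed, 94 moved, 4 became stronger and 3 weaker, and no difference between pluripotency and lineage lists changed sign. A level or lineage difference stayed if it lay within 1 SD, over the 2 replicates, of its main value. A replicate alone always lies within that. All 24 levels and 8 lineage differences therefore had to stay with either replicate left out. The level of a list with no member listed at 0 could not move when such members were left out. At 10 RPKM or more 0 chromosomes lay outside. Depth limits low genes: at 1 RPKM a 2-kb model holds about 6 reads.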

Other observations

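The gene groups in this part, the tests of nearby copies and their levels, of locus length and of chance among lists, and the fibroblast test were chosen after the data were seen. Hox genes, which pattern the body axis, were mostly listed at or near 0: 1 of 31 reached a mean of 1 RPKM, Hoxd9 at 2.61 and 3.32 RPKM, and 23 were listed at 0. Of 8 genes comprising classical cadherins and Epcam, 4 reached 1 RPKM and 2 reached 10 RPKM: Epcam at 478 and 452 RPKM and Cdh1 (E-cadherin) at 157 and 169.97 RPKM. Cdh2 (N-cadherin) was at 1.38 and 0.899 RPKM and Cdh3 (P-cadherin) at 0.844 and 0.931 RPKM. Of 27 integrin family genes 10 reached 1 RPKM, led by Itgb1 (47.2 and 53.7 RPKM) and Itga6 (42.6 and 42.8 RPKM), subunits of a laminin receptor. Of 4 FGF receptor genes Fgfr1 was highest at 119 and 109 RPKM, followed by Fgfr3 at 12.7 and 13.1 RPKM. Fgfr2 was at 1.401 and 1.10 RPKM and Fgfr4 at 1.17 and 1.25 RPKM.

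All 10 Nodal and Activin pathway genes reached 1 RPKM, among them Gdf3 (151 and 159.5 RPKM), Lefty1 (122 and 117 RPKM) and Nodal (47.5 and 47.2 RPKM), while Smad3 (1.37 and 1.76 RPKM) lay far below Smad2 (25.7 and 27.3 RPKM). All 11 serine and one-carbon enzyme genes reached 10 RPKM, with Psat1 highest at 420.2 and 439 RPKM, and so did all 11 lipid synthesis genes, with Scd at 832 and 836 RPKM. The median of detected genes was 13.1 and 12.6 RPKM on the X chromosome (351 genes) and 16.9 and 16.7 RPKM on the autosomes (10463 genes).

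Some genes that every cell uses were listed at or near 0: of 76 ribosomal protein genes, without 7 related genes left out after their values were seen, 9 had a mean under 1 RPKM and 6 were listed at 0. Across all 83 the level did not fall detectably with the number of named pseudogenes (Spearman's rho across genes -0.0549, permutation p = 0.623; -0.0491 with locus length taken out), but the bootstrap interval of -0.284 to 0.162 holds falls as well as rises, so the bound set in advance, a p of 0.05 or more, could not exclude pseudogenes, and with a permutation p of 0.0910 for locus length itself, 0.0395 in the 76, short models stay open too. Named genes with a copy described as "-like" within 1 Mb were under 1 RPKM in 91 of 114 cases, against 72 of 280 with such copies elsewhere only (Fisher's exact test, 2-sided, p = 2.73e-23) and 8303 of 17559 with none (p = 2.01e-12), a contrast that gene families not used in these cells may also produce; among the 76 it was 5 of 6 against 4 of 70 (p = 3.90e-05). Of those 5 only Rps6 had a near copy at 1 RPKM or more (LOC100911372, 12.4 and 11.2 RPKM), which argues against near copies taking the reads for most of these 5. The levels of their copies elsewhere were not examined, so reads taken by those copies stay open. Of the 91 genes 80 had no near copy at 1 RPKM. Gene families not used in these cells give this whatever happens to the reads, so that count decides nothing. Of the other 11, 3 had a near copy at 10 RPKM or more, among them Slc2a3, whose copy LOC100909595 was at 423 and 430.2 RPKM. A candidate explanation is that reads mapping to both copies were lost from both. Copies were found by description only and their sequences were not compared, so whether they share reads is not known. A near copy does not account for the other 4 low genes, of which Rps28, Rps19 and Rpl30 had 6, 8 and 7 such copies elsewhere. Whether copies elsewhere cost these genes reads was not tested.

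The fibroblast and feeder cell markers sat higher in replicate 2, at the 99.8th percentile (99.84) of matched random lists, and Vim (1.12 and 2.01 RPKM) and Thy1 (1.01 and 1.73 RPKM) moved with Fn1 and the collagens, while below 1 RPKM Twist1, Postn and Fbn1 rose and Dcn, Lox and Pdgfrb fell, from 0.207, 0.187 and 0.125 RPKM to 0. More feeder cells in that culture may explain this, but the percentile restates the pattern and cannot decide it; of the 15 markers only Fn1 was above 10 RPKM, and Col1a2, Lum, Acta2 and S100a4 were listed at 0 in both, which may be failed estimates. Chance among the 21 lists compared could also account for it, since 6.56% of random draws held a list as far out. A trend with gene model length could not be tested, as only 1 member had a recovered length, though with a line on locus length removed, a different measure, the list lay at the 99.8th percentile. Cell mixture was thus not decided, and no other biological explanation was tested, since both samples are 1 group.

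The ratio between the replicates was weakly related to length. Across 5 groups of 6499 genes by rising recovered gene model length the median log2 ratio was -0.03, -0.03, -0.02, -0.03 and -0.01. The value was highest in the group with the longest models, with no steady rise across the others, and differences between groups were not tested. A line rose by 0.01 per doubling. Across these genes rho with recovered gene model length was 0.0321, inside the range of 1000 simulated pairs with counting noise only, but 11 of those pairs were as extreme (permutation p across genes 0.00940), so the range set in advance was a lenient bound and counting noise stays open. With locus length rho was 0.0825 across all 10814 detected genes (permutation p = 1e-05, the smallest the permutations can give) and 0.0547 in the 6499, outside the highest simulated value of 0.0519, which argues against counting noise alone for that measure. Leaving out ribosomal protein genes and genes over 100 RPKM gave 0.0303, which decides nothing because the full value already lay inside the range. A difference in RNA fragmentation or library preparation may be the cause, but 0 samples have an integrity number or insert size in the labels, so it cannot be told apart from other differences between the libraries.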
